A study of Mus musculus with 30 samples.

How the data were processed

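RNA from mouse embryonic fibroblasts was measured on 30 Affymetrix expression arrays in 3 experiments: a time course (10 arrays), the lincP21KD siRNA experiment (8 arrays) and the hnRNPKKD siRNA experiment (12 arrays). The deposited values are log2 RMA signal, computed by the authors per the submitters' processing notes, and the RMA version is not given in the sources used here. Array medians lay between 4.976 and 5.032 in the time course, 5.546 and 5.656 in the lincP21KD experiment and 4.832 and 4.914 in the hnRNPKKD experiment, and no comparison was made across experiments on the level of a gene. Differences between experiments were tested only as differences between fold changes that each had their own controls. The deposited values were used without further scaling.

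The table held 45101 probe sets. Of these, 34958 had 1 gene symbol, 932 had several and 9211 had none, and 34754 of the single-gene probe sets had an updated gene entry in the annotation used (GRCm38.p6). Each of the 18194 genes was represented by its probe set with the highest mean over all arrays. The lowest 40% of probe sets by mean were left out, which put the limit at a log2 value of 4.544 and left 12674 tested genes. On arrays the precision of a fold change rests on the number of arrays and on the signal over background, and the standard errors printed beside the values carry both. Trp53cor1, Trp53, Bax, Gdf15 and Ccnb1 are not named in the probe table and are not analysed here, and an experiment with RAS described in the study text is not used here.

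Linear models were fitted with limma 3.58.1 in R 4.3.3 with plain eBayes, separately for each experiment, and p-values were adjusted over all tested genes by the method of Benjamini and Hochberg. A gene was called at an adjusted p below 0.05, and the text writes rose or fell only for called genes. In the time course the virus effect was fitted with the 5 time points as a block, which pairs the 2 viruses at each time. Slopes on hours were fitted within each virus, and the interaction of virus and hours tested whether the slopes differed. In each siRNA experiment all groups were in 1 fit and each knockdown was compared with the control siRNA of that experiment. The differences between the experiments in the siP53 and siLincp21 effects were contrasts in a joint fit of both experiments.

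The 28 gene lists and their minimum of 4 measured genes were written before the data were examined, as were the groups, comparisons and the alternatives except those named below as later choices. They covered p53 activated targets, mitotic genes, DNA replication genes, apoptosis, DNA repair and checkpoint, interferon response, inflammatory and NF-kB genes, immediate early genes, extracellular matrix, contractile and TGF-beta genes, replication-dependent histones, ribosomal proteins, proteasome, sterol synthesis, unfolded protein and amino acid stress, hypoxia, NRF2 targets, hnRNP and splicing factors, chromatin regulators, genes near Cdkn1a, Y-linked genes with Xist, and markers of macrophages, endothelium, epithelium, skeletal muscle, neural cells, adipocytes and chondrocytes. Lists were tested with camera at a preset correlation of 0.01 and adjusted over lists within each comparison. The p with an estimated correlation is given beside the list calls that the text describes. Counts of members use calls over all genes, and counts adjusted over the list alone stand beside them.

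Genes were named by a rule fixed in advance. It takes Hnrnpk and Cdkn1a in every comparison and the 6 highest and 6 lowest called genes without overlap between the groups, or with the same sign at all 5 times in the time course, with no such condition for slopes. It adds up to 4 members with the smallest adjusted p from each list described and the 8 genes with the largest mean absolute change among shared calls. Predicted genes without a proper symbol were passed over. Of the genes this gives, the text prints the ones it describes. Genes that fall outside this rule are marked where they stand as chosen after their values were seen. Other probe sets of a named gene could change far less, and the text prints them beside only some genes. They went down to 1.58 for Trp53inp1 with restoration, and in the lincP21KD experiment to 0.78 for Mfap5 with siP53 and -0.46 for Mbnl3 with siLincp21. In the hnRNPKKD experiment they went to 0.92 for Ednrb with siP53, 0.87 for Prps2 with siLincp21 and 0.77 for Prune2 with siHnrnpk.

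Overlaps of calls were compared with the number expected for independent calls and with 100 simulated sets of unchanged groups that share controls. Replicate numbers were checked for pairing from the correlation of deviations from group means between arrays with the same number. The labels do not say that a number marks a shared culture or day. All 3 pairs lay over 0.1 only for siHnrnpk and its controls (0.216, 0.166 and 0.209), so there the numbers may be read as pairs, from the data and not from the design.

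The alternatives were other filters, other ways of choosing probe sets, quantile scaling and centring on medians, eBayes with trend and robust variances, array weights, stricter thresholds, fits of the 2 groups alone, replicate blocks, fits without the time block, log2 hours, fry, camera with an estimated correlation, and leaving out each array or time. A covariate from the beta-actin 3′ and 5′ control probe sets and sets of p53-responsive genes were added after the data were seen. The models were tested on simulated data with known changes.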

Results

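Mouse embryonic fibroblasts carrying p53 alleles that stay silent until Cre recombinase acts were used to ask which genes respond to p53, and which of these also respond to knockdown of lincRNA-p21 or of the RNA-binding protein hnRNP-K. The cells came from E13.5 embryos and received an adenovirus with Cre (AdenoCre), which restores p53, or with GFP (AdenoGFP). The analysis covered 30 arrays. A time course paired the 2 viruses at 0, 1, 3, 6 and 9 h of 500 nM doxorubicin, with 1 array for each virus and time. The viruses also differ in Cre and GFP, and the time course has no cells with Cre but without p53. In it p53 restoration therefore cannot be told apart from other effects of the viruses. The siP53 comparisons do not rest on the 2 viruses. In the lincP21KD experiment AdenoCre cells received siRNA against p53 (3 arrays), lincRNA-p21 (3 arrays) or a scrambled sequence (2 arrays), followed by 100 nM doxorubicin for 13 h. The hnRNPKKD experiment had 3 arrays each for siRNA against p53, lincRNA-p21, hnRNP-K and a control. The sources do not say whether the replicates were separate cultures, so each p-value measures only the spread between these arrays. Fold changes are log2 with standard errors from limma, and p-values are adjusted over the 12674 tested genes unless stated otherwise. The transcripts of p53 (Trp53) and of lincRNA-p21 (Trp53cor1) are not analysed here. The p53 knockdown was judged only from other genes, and how far lincRNA-p21 was reduced could not be judged. Changes with siLincp21 are therefore changes with this siRNA.

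Most of the measured genes that p53 is known to activate rose in AdenoCre compared with AdenoGFP cells. Cdkn1a, which encodes the cell cycle inhibitor p21, was 3.85 ± 0.15 higher in AdenoCre than in AdenoGFP cells over 5 pairs (adjusted p = 3.5e-05), and the difference was 3.50, 3.46, 3.96, 4.49 and 3.83 at 0, 1, 3, 6 and 9 h. Among all called genes with the same sign at every time, the largest increases were in the ectodysplasin receptor Eda2r (4.49 ± 0.31, adjusted p = 0.000218), the spindle-associated Psrc1 (3.98 ± 0.33), the mTOR inhibitor Ddit4l (3.83 ± 0.41), the stress protein Trp53inp1 (3.69 ± 0.29) and the apoptosis effector Perp (3.50 ± 0.30). The largest decreases among them were in the growth factor receptor genes Gfra2 (-2.19 ± 0.14; its other probe sets to -0.27) and Pdgfra (-1.88 ± 0.13, adjusted p = 0.000218), the matrix protein Tgfbi (-1.72 ± 0.19), Lgr5 (-1.60 ± 0.20), lipoprotein lipase Lpl (-1.55 ± 0.11) and the chemokine Cxcl5 (-1.54 ± 0.14). Hnrnpk was -0.33 ± 0.12 and did not pass (adjusted p = 0.0819), but it was called lower after centring of the arrays (-0.437), with trend and robust variances (-0.33) and with array weights (-0.474). Its adjusted p ran from 0.0146 to 0.264 over the alternatives.

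Of 38 measured p53 target genes, 30 rose with p53 restoration, 0 fell and 8 did not pass, and adjusted over the list alone 32 rose and 2 fell. Ephx1, a detoxifying hydrolase, rose by 3.23 ± 0.18, the adenylate kinase Ak1 by 2.40 ± 0.14 and the Akt inhibitor Phlda3 by 2.00 ± 0.12. The median of the list was 1.34 (camera adjusted p = 4.53e-18, and adjusted p = 0.372 with an estimated correlation). Of 24 apoptosis genes 10 rose and 0 fell (11 rose adjusted over the list alone), among them Bbc3 (1.07 ± 0.13), which encodes the BH3-only protein PUMA, and the death receptor Tnfrsf10b (1.31 ± 0.17). Both are also in the p53 target list, as are Fas, Perp and other members, so the 2 lists are not independent. The median of the apoptosis list was 0.217 (adjusted p = 0.0421, and adjusted p = 0.372 with an estimated correlation). Its call ended without the 0 h pair (median 0.185) or the 9 h pair (median 0.268). Of 4 replication-dependent histone genes 3 rose, in both counts, with H2aw at 1.20 ± 0.24 and H1f2 at 1.10 ± 0.17. Their median of 1.14 (adjusted p = 0.039, and adjusted p = 0.372 with an estimated correlation) lost its call without the 1 h pair (median 1.14) and with array weights (0.867).

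In AdenoCre compared with AdenoGFP cells 13 mitotic, 11 DNA replication, 20 interferon and 12 sterol synthesis genes fell. Of 31 mitotic genes 13 fell and 0 rose, with 19 falling when adjusted over the list alone. The guanine nucleotide exchange factor Ect2 (-0.91 ± 0.13) and the kinase Aurkb (-0.51) were among those that fell. Aurkb did not pass without the time block (-0.514). The mitotic median was -0.319 (adjusted p = 9.57e-12, and adjusted p = 0.372 with an estimated correlation) and reached -0.694 at 9 h. Of 40 DNA replication genes 11 fell and 0 rose (16 fell adjusted over the list alone), including the helicase subunit Mcm4 (-0.75 ± 0.11) and the clamp loader subunit Rfc4 (-0.63 ± 0.09). Their median was -0.352 (adjusted p = 4.56e-12, and adjusted p = 0.424 with an estimated correlation). Of 31 interferon-stimulated genes 20 fell and 1 rose over the 5 pairs (24 and 2 adjusted over the list alone). Their median was -0.662 in the single pair of arrays at 0 h, where no test was made. The antiviral genes Ifit1 (-1.53 ± 0.11), Oasl2 (-1.49 ± 0.09) and Rtp4 (-1.51) fell, and the list median was -0.644 (adjusted p = 5.99e-15, and adjusted p = 0.15 with an estimated correlation). Of 15 sterol synthesis genes 12 fell and 0 rose in both counts, with Insig1 at -1.07 ± 0.18, Cyp51 at -0.80 ± 0.13 and Sqle at -0.66 ± 0.10. Insig1 did not pass without the time block (-1.067). The sterol median was -0.666 over all times (adjusted p = 3.99e-10, and adjusted p = 0.372 with an estimated correlation) and -1.10 at 9 h.

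Smaller shifts followed in RNA-binding, chromatin, stress and repair genes. Of 26 hnRNP and splicing genes 7 fell and 0 rose in both counts. As a list they had a median of -0.219 (adjusted p = 3.25e-06, and adjusted p = 0.15 with an estimated correlation), led by Hnrnpr (-0.72 ± 0.14). Of 22 chromatin regulators 4 fell in both counts, including Cbx1 (-0.60), which did not pass without the 3 h pair (-0.54) or as the mean of its probe sets (-0.097). Their median was -0.158 (adjusted p = 0.000648, and adjusted p = 0.372 with an estimated correlation). Of 22 unfolded protein and amino acid stress genes 7 fell and 1 rose (11 and 1 adjusted over the list alone). The pseudokinase Trib3 was at -1.04 ± 0.15, and without the time block at -1.041 and not called. The median of the stress list was -0.224 (adjusted p = 0.00182, and adjusted p = 0.372 with an estimated correlation). Of 23 DNA repair and checkpoint genes 3 fell and 1 rose (6 and 1 adjusted over the list alone), with Ercc1 at 0.51, and the median was -0.16 (adjusted p = 0.00472, and adjusted p = 0.575 with an estimated correlation). Hypoxia genes were split, with Pdk1 at -1.26 and Ddit4 at 0.82. The median of 21 was -0.052 (adjusted p = 0.0421, and adjusted p = 0.586 with an estimated correlation), and the call ended without the 0 h pair (-0.045) or the 9 h pair (-0.026), after quantile scaling (-0.084) and without the time block (-0.052). Of 17 contractile and TGF-beta genes 6 rose (7 adjusted over the list alone), such as calponin Cnn1 (0.54) and Tgfb1 (0.63). Their median was 0.133 (adjusted p = 0.039, and adjusted p = 0.372 with an estimated correlation), with no call without the 0 h pair (0.136) or the 9 h pair (0.16). It also ended with the 60% filter (0.133), with centred arrays (0.025) and with array weights (0.126).

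The remaining gene groups were not called as lists between the viruses. Inflammatory genes were mixed, with 8 of 21 rising and 4 falling (median 0.25, adjusted p = 0.246); Lif rose by 1.36 while Cxcl5 fell. Immediate early genes rose in 6 of 21 (0.219, adjusted p = 0.0756), extracellular matrix genes rose in 3 and fell in 4 of 25 (-0.031, adjusted p = 0.133), and NRF2 targets rose in 3 and fell in 2 of 14 (0.146, adjusted p = 0.16). Of 20 ribosomal protein genes (0.022, adjusted p = 0.895) and 24 proteasome genes (0.004, adjusted p = 0.389) 0 passed, and for both the test pointed downwards while the median was above 0. The list of genes near Cdkn1a, which includes Cdkn1a itself, was not called, with 1 rising and 1 falling among 9 (median -0.033, adjusted p = 0.875). The gene that rose was Cdkn1a, and with it included the mean was positive. Among cell type markers, epithelial keratins went in opposite directions (Krt19 1.36, Krt7 0.96, Krt8 -0.64, Krt18 -1.05), so their median of -0.121 and their mean of 0.065 differed in sign (adjusted p = 0.625). Macrophage markers rose in 2 of 8 (0.057, adjusted p = 0.94), skeletal muscle markers in 1 of 6 (0.213, adjusted p = 0.474) and neural markers rose in 1 and fell in 1 of 10 (0.046, adjusted p = 0.94). Endothelial markers passed in 0 of 4 (0.002, adjusted p = 0.94; the test pointed downwards), adipocyte markers rose in 1 and fell in 1 of 5 (-0.07, adjusted p = 0.487), chondrocyte markers fell in 1 of 8 (-0.187, adjusted p = 0.107), and the Y-linked genes and Xist passed in 0 of 4 (-0.246, adjusted p = 0.133).

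Over the genome 2427 genes were called between the viruses, 1636 higher and 791 lower, of which 272 changed at least 2-fold. The share of higher calls was 67.4% and depended on scaling, at 51.5% after quantile scaling and 45.2% with arrays centred on their medians. Centring moved the median of all genes from 0.04 to -0.067. Without the 3 h pair 1146 genes were called, without the 6 h pair 1444 and without the 9 h pair 1511. The AdenoGFP array at 6 h had the lowest median over tested genes, 8.016 beside 8.199 to 8.333 on the other time course arrays, and without its pair Cdkn1a, the p53 targets, the interferon genes and the sterol genes kept their calls.

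**Figure D1:**
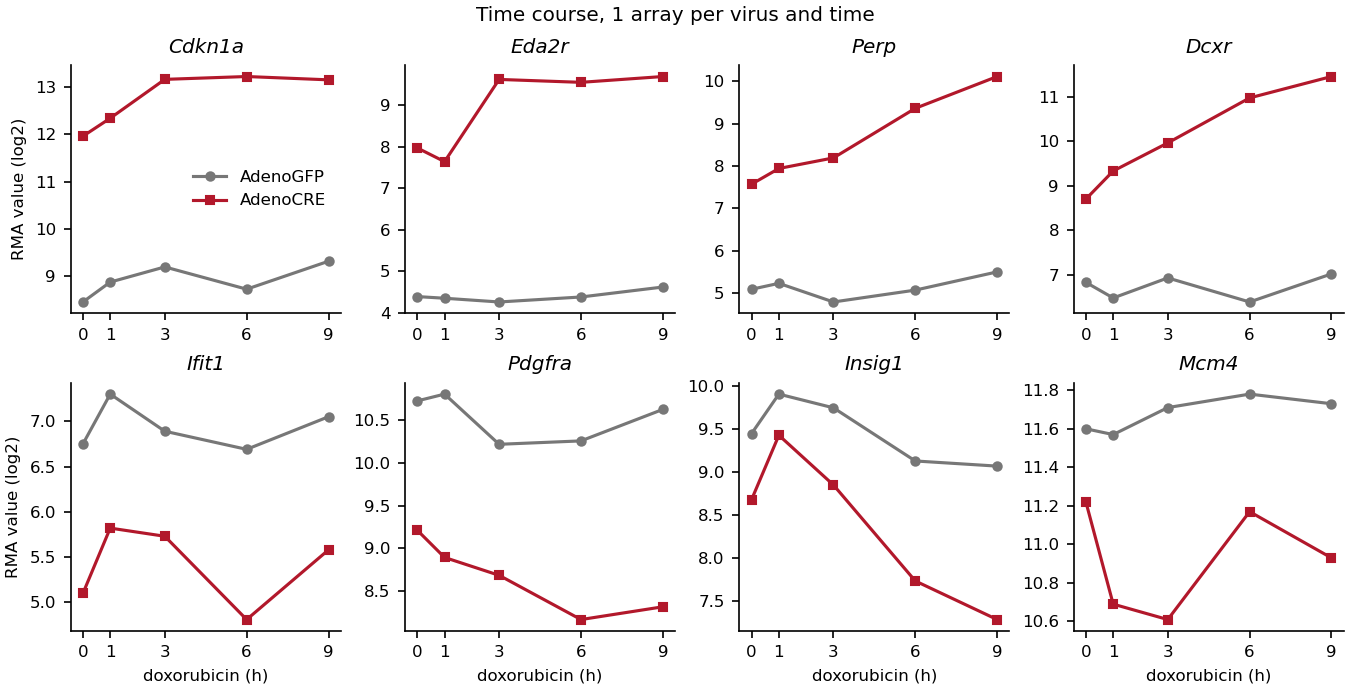
Deposited RMA log2 signal (vertical axis) of 8 genes against hours of doxorubicin (horizontal axis), 1 array per point, for AdenoCre and AdenoGFP cells. Cdkn1a differed by 3.50 at 0 h and 3.83 at 9 h, and Perp by 2.47 at 0 h. Ifit1 was lower by 1.65 already at 0 h.

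Changes with doxorubicin time were tested within each virus and then between the viruses. In AdenoCre cells 684 genes changed with time over 9 h, 500 upwards and 184 downwards, whereas in AdenoGFP cells 1 gene did (Tcaf2, 0.17 ± 0.01 per h, adjusted p = 0.00947) although 1654 had an unadjusted p below 0.05 in limma. The steepest increases with p53 were in the Rab GTPase-activating protein Tbc1d8 (0.50 ± 0.05 per h, adjusted p = 0.00121), the RNA-binding Celf5 (0.49 ± 0.04), the adhesion molecule Icam1 (0.48 ± 0.05), the peroxisomal thiolase Acaa1b (0.47 ± 0.03), the phosphatase subunit Ppp2r2c (0.47 ± 0.05) and the pantetheinase Vnn1 (0.46 ± 0.04). Among the steepest decreases were Cemip (-0.23 ± 0.04), Trib3 (-0.22 ± 0.05) and Insig1 (-0.21 ± 0.04). These calls ended for Cemip without 0, 3 or 9 h (-0.262, -0.23 and -0.306), for Trib3 without 0, 6 or 9 h (-0.252, -0.205 and -0.27) and for Insig1 without 1, 6 or 9 h (-0.177, -0.2 and -0.208). On log2 hours none of these 3 passed (-0.603, -0.57 and -0.498 per unit). Cdkn1a itself did not pass with p53 (0.13 ± 0.04 per h, adjusted p = 0.107) or without it (0.06 ± 0.04, adjusted p = 0.565). With p53 it was called as the mean of its probe sets (0.143) and on log2 hours (0.401 per unit), with adjusted p from 0.0351 to 0.356 over the alternatives. Tcaf2 in AdenoGFP cells did not pass without any 1 of the 5 times (0.162 to 0.169) or on log2 hours (0.432 per unit). Left-out times moved the AdenoCre count to 216, 204, 354, 424 and 267 without 0, 1, 3, 6 and 9 h.

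In AdenoCre cells some p53 targets rose and some sterol genes fell with time after damage. Of 38 p53 targets 16 rose with time in AdenoCre cells and 0 fell (27 rose adjusted over the list alone), including the carbonyl reductase Dcxr (0.30 ± 0.03 per h), Perp (0.28 ± 0.03) and the death receptor Fas (0.25). Their median slope was 0.115 (adjusted p = 6.61e-15, and adjusted p = 0.226 with an estimated correlation). Of 15 sterol genes 6 fell and 0 rose (9 fell adjusted over the list alone), among them Hmgcs1 (-0.15), which did not pass without 9 h (-0.138) or on log2 hours (-0.357 per unit). Their median was -0.083 per h (adjusted p = 8.17e-08, and adjusted p = 0.381 with an estimated correlation). Interferon genes turned upwards with time, with 5 of 31 rising in both counts, including Tap1 (0.32) and Usp18 (0.26), and a median of 0.031 (adjusted p = 0.00143, and adjusted p = 0.404 with an estimated correlation), a call lost without 0 h (0.018). Their slope was not called different between the viruses (-0.003, adjusted p = 0.256), and the median gap was -0.662, -0.578, -0.484, -0.581 and -0.675 at 0, 1, 3, 6 and 9 h. In AdenoGFP cells 0 list members passed, but 21 of 40 DNA replication genes rose when adjusted over the list alone, with a median slope of 0.08 (adjusted p = 1.37e-16, and adjusted p = 0.444 with an estimated correlation).

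Further lists were called for the AdenoGFP slope with 0 members passing over all genes. Interferon genes rose as a list (median 0.032 per h, adjusted p = 0.0197, and adjusted p = 0.578 with an estimated correlation), as did DNA repair genes (0.042, adjusted p = 0.00877, and adjusted p = 0.631 with an estimated correlation), where 1 member passed adjusted over the list alone. Immediate early genes fell as a list (-0.095, adjusted p = 6.8e-05, and adjusted p = 0.631 with an estimated correlation), as did contractile genes (-0.027, adjusted p = 0.00581, and adjusted p = 0.578 with an estimated correlation). Amino acid stress genes (-0.04, adjusted p = 1.08e-05, 1 member adjusted over the list alone) and hnRNP and splicing genes (-0.029, adjusted p = 7.96e-05) also fell as lists, each with adjusted p = 0.444 with an estimated correlation. Without 9 h none of these 6 calls held, with medians of 0.017 for interferon, 0.006 for DNA repair, -0.121 for immediate early, -0.025 for contractile, -0.049 for stress and -0.035 for hnRNP genes.

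The direct test of whether the time response differed between the viruses called 23 genes, all with a steeper slope in AdenoCre cells. They included the TNF receptor family member Tnfrsf18 (0.49 ± 0.04 per h, adjusted p = 0.00587), Celf5 (0.49 ± 0.06), Tbc1d8 (0.45 ± 0.07) and Perp (0.25 ± 0.04, adjusted p = 0.0383). In that order, none of these 4 passed without 0 h (0.521, 0.472, 0.468 and 0.24), 1 h (0.485, 0.509, 0.439 and 0.243) or 9 h (0.496, 0.604, 0.607 and 0.308). Without 3 h Celf5 (0.481), Tbc1d8 (0.442) and Perp (0.251) did not pass, and without 6 h Perp (0.236). On log2 hours none of the 4 passed (1.265, 1.311, 1.194 and 0.681 per unit). Cdkn1a did not pass in this test (0.07 ± 0.06, adjusted p = 0.822). As a list the p53 targets were steeper by a median of 0.106 per h (adjusted p = 9.26e-18, and adjusted p = 0.459 with an estimated correlation), with 1 gene passing and 9 when adjusted over the list alone. DNA replication genes were lower by a median of -0.07 (adjusted p = 3.9e-12, and adjusted p = 0.459 with an estimated correlation) and sterol genes by -0.082 (adjusted p = 3.92e-07, and adjusted p = 0.459 with an estimated correlation), with 0 members passing in either. The count was fragile, with 0 genes without 0 h, 0 without 1 h, 3 without 3 h and 7 without 9 h.

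Knockdown of p53 in the lincP21KD experiment asked which genes need p53 in damaged cells, at another dose and time of doxorubicin than in the time course. Part of the genes called by restoration went the other way. Cdkn1a fell by 2.07 ± 0.11 (3 arrays beside 2 controls, adjusted p = 4.91e-06), with levels of 10.53, 10.31 and 10.68 on the siP53 arrays beside 12.48 and 12.68 on the controls. The largest decreases among called genes without overlap between the groups were in Dcxr (-3.00 ± 0.15), the testis-type cytochrome oxidase subunit Cox6b2 (-2.61 ± 0.13), Celf5 (-2.53 ± 0.11), Acaa1b (-2.47 ± 0.12), Perp (-2.37 ± 0.11) and the p53 ubiquitin ligase Mdm2 (-2.36 ± 0.15). The largest increases were in the interferon gene Ifit1 (2.43 ± 0.22, adjusted p = 0.000114), the chemokine Cxcl15 (2.38 ± 0.18), the microfibril protein Mfap5 (2.21 ± 0.08), Ifit3 (2.07 ± 0.14), the cysteine dioxygenase Cdo1 (1.90 ± 0.12) and Oasl2 (1.86 ± 0.30). Of the 2427 genes called by restoration 678 were also called here. Of these 678 genes 619 went in opposite directions, where 149 were expected for independent calls.

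Of 38 p53 targets 29 fell and 1 rose with siP53 (32 and 1 adjusted over the list alone), including Ei24 (-1.25 ± 0.07), and the median was -0.982 (adjusted p = 7.16e-29, and adjusted p = 0.201 with an estimated correlation). Interferon-stimulated genes rose in 23 of 31 and fell in 1 (26 and 1 adjusted over the list alone). The GTPase Iigp1 rose by 1.37 ± 0.15, whereas the peptide transporter Tap1, itself a known p53 target, fell by 1.04 ± 0.11 and did not pass as the mean of its probe sets (-0.205). The median was 0.93 (adjusted p = 7.51e-16, and adjusted p = 0.266 with an estimated correlation). Sterol genes rose in 8 of 15 and fell in 0 (15 rose adjusted over the list alone), with Idi1 at 0.99 ± 0.17 and Fdps at 0.68 ± 0.09. Over the list the median was 0.631 (adjusted p = 4.04e-08, and adjusted p = 0.266 with an estimated correlation). Mitotic genes rose in 12 of 31 and fell in 0 (26 rose adjusted over the list alone), led by the kinase Nek2 (0.88 ± 0.08) and the kinetochore gene Ndc80 (0.61). Their median was 0.364 (adjusted p = 9.38e-12, and adjusted p = 0.266 with an estimated correlation). Matrix genes rose in 7 of 25 (9 adjusted over the list alone), such as decorin Dcn (0.88) and Col3a1 (0.63). Their median was 0.166 (adjusted p = 0.000684, and adjusted p = 0.266 with an estimated correlation). Immediate early genes fell in 5 of 21 (8 adjusted over the list alone), with Fos at -0.83. The median over members was -0.207 (adjusted p = 0.00415, and adjusted p = 0.266 with an estimated correlation). In all 1615 genes were called, 888 higher and 727 lower, and 620 or 701 without the first or second control array.

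Knockdown of lincRNA-p21 in the same experiment asked which genes change when this transcript, a p53 target next to Cdkn1a, is reduced. Cdkn1a did not pass (0.01 ± 0.11, 3 arrays beside 2 controls, adjusted p = 0.98), with levels of 12.66, 12.57 and 12.52. The largest increases were in the metalloprotease inhibitor Reck (1.60 ± 0.13, adjusted p = 0.000383), the anthrax toxin receptor Antxr2 (1.57 ± 0.14), the pyrimidine-degrading Dpyd (1.55 ± 0.22), the stress genes Trib3 (1.44 ± 0.24) and Chac1 (1.40 ± 0.21), and the collagen gene Col11a1 (1.39 ± 0.09). The largest decreases were in proenkephalin Penk (-1.61 ± 0.29, adjusted p = 0.00699), Cystm1 (-1.57 ± 0.13; its other probe set -0.19), the splicing factor Mbnl3 (-1.57 ± 0.14), Snn (-1.44 ± 0.13), the protease inhibitor Serpinb2 (-1.43 ± 0.19) and Dynap (-1.43 ± 0.15). The p53 targets were not called as a list, with 4 rising, 4 falling and 30 not passing (6 and 6 adjusted over the list alone). Their median was 0.008 (adjusted p = 0.812, the test pointing downwards). Perp (-0.53) and Ei24 (-0.47) fell as with siP53, while Rap2b (0.55) rose. Without control replicate 1 the calls of Trib3 (1.475), Chac1 (1.191), Penk (-1.674) and Rap2b (0.472) ended, and without control replicate 2 those of Penk (-1.543) and Perp (-0.388).

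With siLincp21 in this experiment 9 stress, 9 matrix and 6 mitotic genes rose. Unfolded protein and amino acid stress genes rose in 9 of 22 and fell in 0 (11 and 1 adjusted over the list alone), including Atf5 (0.94 ± 0.13), the asparagine synthetase Asns (0.73 ± 0.08) and Ddit3 (0.62 ± 0.08). Their median was 0.265 (adjusted p = 0.000198, and adjusted p = 0.449 with an estimated correlation). Matrix genes rose in 9 of 25 (10 rose and 2 fell adjusted over the list alone), with Col3a1 at 0.78 and Fstl1 at 0.67. Across the group the median was 0.151 (adjusted p = 0.00229, and adjusted p = 0.449 with an estimated correlation). Mitotic genes rose in 6 of 31 and fell in 0 (9 rose adjusted over the list alone), including Nek2 (0.61 ± 0.08). Their median was 0.195 (adjusted p = 0.00163, and adjusted p = 0.668 with an estimated correlation). Immediate early genes fell in 6 of 21 in both counts, with Fos at -0.59 and, without control replicate 1, at -0.548 and not called. The group had a median of -0.135 (adjusted p = 0.00229, and adjusted p = 0.449 with an estimated correlation). Of 6 epithelial markers 1 fell and 0 rose (2 fell adjusted over the list alone), with a median of -0.164 (adjusted p = 0.0468, and adjusted p = 0.449 with an estimated correlation). That call ended without control replicate 1 (-0.23) or siLincp21 replicate 3 (-0.143), after quantile scaling (-0.202) or centring (-0.219), with array weights (-0.155) and under the replicate block (-0.131). Sterol genes fell in 3 of 15, among them the regulator Srebf2 (-0.38), the opposite of siP53. Srebf2 did not pass without control replicate 1 (-0.299) or siLincp21 replicate 1 (-0.383), or as the mean of its probe sets (-0.28). On siLincp21 replicate 3 the sterol median was -0.052 (others -0.364 and -0.304) and the mitotic median 0.063 (others 0.274 and 0.29), and its actin 3′ minus 5′ signal was the highest of the experiment at 0.33 (others 0.123 to 0.219). The list median was -0.23 (adjusted p = 0.00226, and adjusted p = 0.658 with an estimated correlation). The 1503 calls, 947 higher and 556 lower, fell to 286 or 511 without the first or second control array and to 798 without the first siLincp21 array. The share of higher calls was 63% and 45.7% with arrays centred on their medians.

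Genes called by siP53 and by siLincp21 numbered 524 in the lincP21KD experiment. Of these, 344 rose with both and 128 fell with both, where 66.4 and 31.9 were expected for independent calls, and 52 went in opposite directions where 93.3 were expected. The chemokine Cxcl15 rose by 2.38 and 1.22 with siP53 and siLincp21, and Antxr2 by 1.41 and 1.57. Decreases with both were seen in Perp (-2.37 and -0.53), the connexin Gjb5 (-1.53 and -0.95) and Serpinb2 (-1.37 and -1.43). Perp did not pass with siLincp21 without control replicate 2 (-0.388). Both knockdowns share the same 2 control arrays, which cannot be split, so part of the excess may come from the shared controls. Simulated unchanged groups with shared controls gave 0 shared calls, which does not measure that part among changed genes. They gave a correlation of 0.6 where 0.361 was seen, and a covariance of 0.00849 where 0.025 was seen. Without the first or second control array 88 or 177 genes were shared in direction instead of 472, and without the first siLincp21 array 314. Against arrays with other controls, 863 genes were called by siP53 of the hnRNPKKD experiment and siLincp21 of this one, of which 492 rose and 188 fell with both (183 and 107 expected). For siP53 of this experiment and siLincp21 of the hnRNPKKD experiment 748 genes were called by both, of which 359 rose and 139 fell with both (153 and 86 expected) and 250 went in opposite directions (230 expected).

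**Figure D2:**
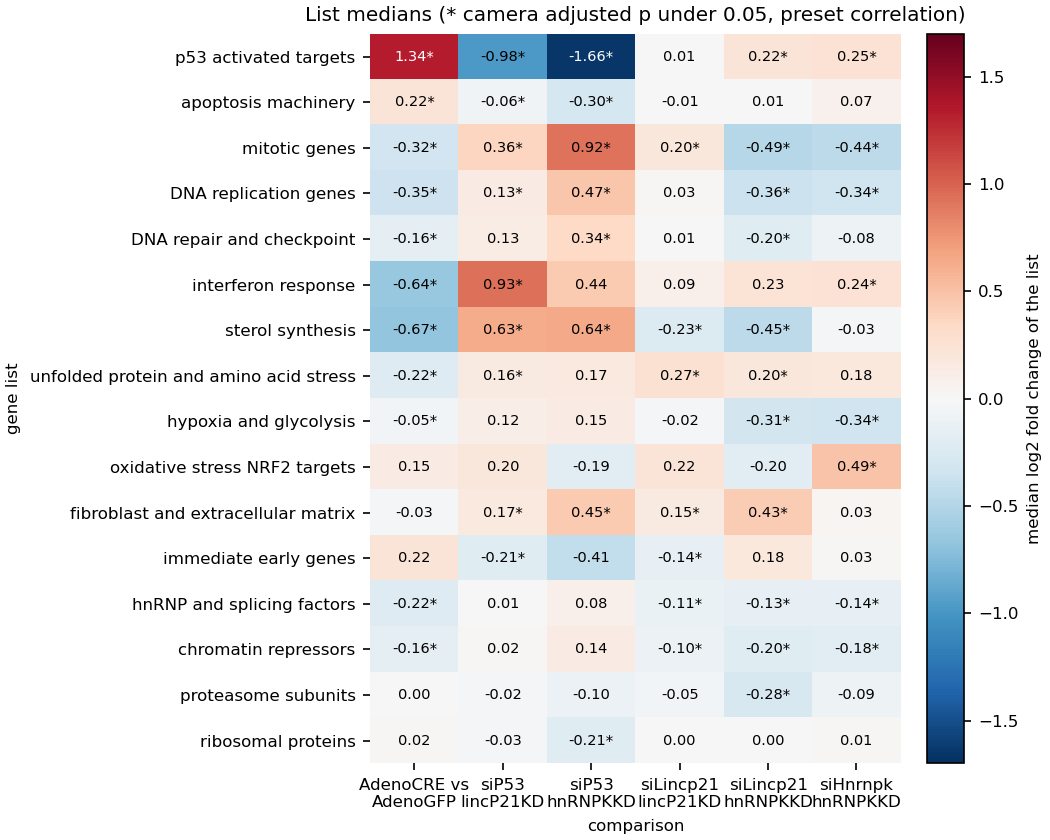
Median log2 fold change (colour scale) of 16 gene lists (vertical axis) in 6 comparisons (horizontal axis); stars mark a camera adjusted p below 0.05. The p53 targets had a median of 1.34 with restoration, and -0.982 and -1.66 with siP53 in the 2 experiments. Mitotic genes had a median of 0.195 with siLincp21 in the lincP21KD experiment and -0.49 in the hnRNPKKD experiment.

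Knockdown of p53 in the hnRNPKKD experiment asked again which genes need p53 in damaged cells. Cdkn1a fell by 2.64 ± 0.18 (3 arrays beside 3, adjusted p = 4.39e-07), with siP53 levels of 10.52, 11.41 and 10.61 beside 13.53, 13.43 and 13.51 on the controls. The largest decreases were in arginase Arg2 (-4.15 ± 0.18, adjusted p = 1.76e-08), Acaa1b (-3.95 ± 0.28), Dcxr (-3.61 ± 0.36), the G protein regulator Rgs5 (-3.60 ± 0.12), Cox6b2 (-3.46 ± 0.40) and Celf5 (-3.45 ± 0.20). The kinase Stk26 rose by 2.68 ± 0.24 (adjusted p = 4.34e-06), the metalloprotease Adam12 by 2.61 ± 0.25, asporin Aspn by 2.61 ± 0.25, Cxcl5 by 2.46 ± 0.25, the endothelin receptor Ednrb by 2.36 ± 0.21 and the elongase Elovl5 by 2.35 ± 0.22. Of 4888 called genes 2450 rose and 2438 fell, and 932 changed at least 2-fold. Of 1475 genes called here and by restoration, 1261 went in opposite directions, where 468 were expected.

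With siP53 in this experiment 28 mitotic and 23 DNA replication genes rose. Mitotic genes rose in 28 of 31 and fell in 0 (30 rose adjusted over the list alone), including Nek2 (1.71 ± 0.14), Aurkb (1.61 ± 0.13) and Kif11 (1.53 ± 0.14). Their median was 0.923 (adjusted p = 2.63e-15, and adjusted p = 0.127 with an estimated correlation). DNA replication genes rose in 23 of 40 and fell in 0 (24 rose adjusted over the list alone), with the polymerase subunit Pola1 at 1.51 ± 0.12 and Orc1 at 1.17. As a list they had a median of 0.474 (adjusted p = 1.88e-08, and adjusted p = 0.093 with an estimated correlation). Of 38 p53 targets 31 fell and 2 rose (32 and 2 adjusted over the list alone), with Perp at -3.27 ± 0.13, Pmaip1 at -2.86 ± 0.16 and Sesn2 at -2.00 ± 0.12. Over the list the median was -1.66 (adjusted p = 1.13e-16, and adjusted p = 0.127 with an estimated correlation). Matrix genes rose in 17 of 25 and fell in 1 in both counts, with Pdgfrb at 1.75 and the lysyl oxidase Lox at 1.67. The median over members was 0.448 (adjusted p = 7.88e-06, and adjusted p = 0.142 with an estimated correlation). Sterol genes rose in 12 of 15 (13 adjusted over the list alone), with Insig1 and Idi1 at 1.41 each. Across the group the median was 0.643 (adjusted p = 8.51e-06, and adjusted p = 0.234 with an estimated correlation). Interferon genes were not called as a list (9 rose and 3 fell of 31, median 0.441, adjusted p = 0.176), and Tap1 fell by 2.23. The siP53 arrays spread in the actin 3′ minus 5′ signal, a sign of RNA quality (0.691, 0.165 and 1.14, controls 0.525, 0.322 and 0.355). Ribosomal protein genes fell in 5 of 20 (3 adjusted over the list alone; median -0.206, adjusted p = 0.0399, and adjusted p = 0.664 with an estimated correlation), a call that ended with this signal as covariate (-0.097), without siP53 replicate 3 (-0.127) and without control replicate 2 (-0.224) or 3 (-0.204). It also ended with centred arrays (-0.186) and in a fit of the 2 groups alone (-0.206).

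Knockdown of lincRNA-p21 in the hnRNPKKD experiment asked the question of the first siLincp21 comparison again with other controls. Cdkn1a did not pass (0.31 ± 0.18, 3 arrays beside 3, adjusted p = 0.213), and its levels were 13.73, 13.81 and 13.86. It was called as higher with array weights (0.278), in a fit of the 2 groups alone (0.315) and with the actin covariate (0.4), with adjusted p from 0.0195 to 0.583 over the alternatives. The nucleoside diphosphate kinase Nme4 rose by 2.72 ± 0.35 (adjusted p = 0.000113), the melanosome regulator Mreg by 2.58 ± 0.18, Igdcc4 by 2.42 ± 0.15, pyruvate carboxylase Pcx by 2.42 ± 0.09 (read by a control probe set of the array), Prps2 by 2.38 ± 0.11 and Mfap5 by 2.18 ± 0.34. Decreases were largest in keratin Krt18 (-3.02 ± 0.13, adjusted p = 3.99e-08), the protease Prss22 (-2.27 ± 0.19), Cfdp1 (-2.12 ± 0.15), the phosphatase Dusp4 (-2.06 ± 0.17), Fam3c (-2.05 ± 0.09; its other probe set -0.44) and Cytip (-1.98 ± 0.14; its other probe sets to -0.11). Between the 2 siLincp21 comparisons 968 genes were called in both and 946 (97.7%) shared their direction, 615 upwards and 331 downwards (163 and 65.8 expected). They included Reck (1.60 and 1.97 in the lincP21KD and hnRNPKKD experiments), Col11a1 (1.39 and 2.10), Taf9b (1.33 and 2.06) and Krt18 (-0.72 and -3.02).

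Unlike in the lincP21KD experiment, 19 mitotic and 18 DNA replication genes fell with siLincp21 here. Mitotic genes fell in 19 of 31 and rose in 0 (24 and 1 adjusted over the list alone), with the kinesin Kif20a at -0.76 ± 0.08 and the kinase Ttk at -0.80 ± 0.11. They had a median of -0.49 (adjusted p = 1.49e-08, and adjusted p = 0.162 with an estimated correlation). DNA replication genes fell in 18 of 40 and rose in 2 (21 and 2 adjusted over the list alone), with Gins1 at -0.93 ± 0.10 and Rfc1 at 1.32 ± 0.16. The group had a median of -0.359 (adjusted p = 1.78e-06, and adjusted p = 0.162 with an estimated correlation). Sterol genes fell in 8 of 15 (9 adjusted over the list alone), with Stard4 at -1.78 ± 0.14 and a median of -0.451 (adjusted p = 8.2e-06, and adjusted p = 0.162 with an estimated correlation). Proteasome genes fell in 8 of 24 in both counts, such as Psmd12 (-0.48). Their median was -0.277 (adjusted p = 0.00139, and adjusted p = 0.162 with an estimated correlation). Matrix genes rose in 15 of 25 and fell in 2 (17 and 2 adjusted over the list alone), Timp3 by 1.42 ± 0.09 and Mmp2 by 0.90. The list median was 0.434 (adjusted p = 6.04e-05, and adjusted p = 0.162 with an estimated correlation). Amino acid stress genes again rose, in 9 of 22 with 1 falling in both counts, with Trib3 at 1.47 ± 0.17 and Asns at 1.14 ± 0.13. As a list they had a median of 0.197 (adjusted p = 0.0226, and adjusted p = 0.162 with an estimated correlation). The p53 targets rose in 13 of 38 and fell in 4 in both counts, with Dram1 at 1.48 and Fbxw7 at 1.01 ± 0.10. Over the list the median was 0.217 (adjusted p = 0.0249, and adjusted p = 0.634 with an estimated correlation), and this call ended without the second control array (0.138). In total 3678 genes were called, 2179 higher and 1499 lower, and the share of higher calls was 59.2%, or 48.1% with arrays centred on their medians. The actin 3′ minus 5′ signal was 0.441, 0.4 and 0.76 on the siLincp21 arrays, and with it as a covariate, chosen after the data were seen, 5683 genes were called.

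Knockdown of hnRNP-K asked which genes depend on this RNA-binding protein. Hnrnpk fell by 3.51 ± 0.35 (3 arrays beside 3, adjusted p = 2.12e-05), with levels of 8.38, 8.34 and 9.94 beside 12.68, 12.03 and 12.47 on the controls, so replicate 3 kept more of the transcript. Its 4 probe sets changed by -3.79 to -0.63. It did not pass with siLincp21 (-0.20 ± 0.35, adjusted p = 0.73). Cdkn1a did not pass with siHnrnpk (0.07 ± 0.18, adjusted p = 0.825; levels 13.54, 13.6 and 13.54). Nme4 rose by 3.34 ± 0.35 (adjusted p = 2.74e-05), the cytochrome P450 gene Cyp2j9 by 2.21 ± 0.13, Prune2 by 2.17 ± 0.18, Prps2 by 2.15 ± 0.11, the sodium channel subunit Scn3b by 2.14 ± 0.23 and Tsacc by 2.12 ± 0.15. The largest decreases after Hnrnpk itself were in Krt18 (-2.91 ± 0.13, adjusted p = 1.71e-07), Svip (-2.83 ± 0.23; its other probe set -0.67), the clathrin adaptor Necap1 (-2.40 ± 0.14), Cyb5r1 (-2.39 ± 0.15) and the deubiquitinase Mindy2 (-2.34 ± 0.19). The comparison called 3408 genes, 1783 higher and 1625 lower, and 5463 with the actin signal as covariate, although that signal was 0.359, 0.339 and 0.303 on the siHnrnpk arrays.

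With siHnrnpk 17 mitotic, 18 DNA replication, 10 hypoxia and 8 chromatin genes fell. Mitotic genes fell in 17 of 31 and rose in 0 (23 fell adjusted over the list alone), with Plk1 at -0.77 and Top2a at -0.73. The median over members was -0.444 (adjusted p = 3.51e-08, and adjusted p = 0.273 with an estimated correlation). DNA replication genes fell in 18 of 40 and rose in 3 in both counts, including Cdc6 (-1.18) and the cyclin Ccne2 (-1.12). Their median was -0.341 (adjusted p = 8.19e-05, and adjusted p = 0.2 with an estimated correlation). Hypoxia genes fell in 10 of 21 and rose in 0 in both counts, with Bnip3 at -1.68 ± 0.13 and Egln3 at -1.20. Across the group the median was -0.344 (adjusted p = 0.00108, and adjusted p = 0.0811 with an estimated correlation). Chromatin regulators fell in 8 of 22 in both counts, with Cbx5 at -1.37 and the methyltransferase Ezh2 at -0.74. The group had a median of -0.177 (adjusted p = 0.00196, and adjusted p = 0.629 with an estimated correlation). Of 26 hnRNP and splicing genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), including Srsf3 (-0.83 ± 0.09) and Hnrnph1 (-0.69). Their median was -0.137 (adjusted p = 0.0147, and adjusted p = 0.252 with an estimated correlation). NRF2 targets rose in 6 of 14 (8 adjusted over the list alone), such as Srxn1 (1.11) and Gclm (0.74). Their median was 0.489 (adjusted p = 0.0147, and adjusted p = 0.335 with an estimated correlation). The p53 targets rose in 11 of 38 and fell in 3 (11 and 4 adjusted over the list alone), with Dram1 at 1.62 ± 0.16 and Rap2b at 1.39 ± 0.11. Their median of 0.251 (adjusted p = 0.0154, and adjusted p = 0.753 with an estimated correlation) lost its call without the second control array (0.203).

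**Figure D3:**
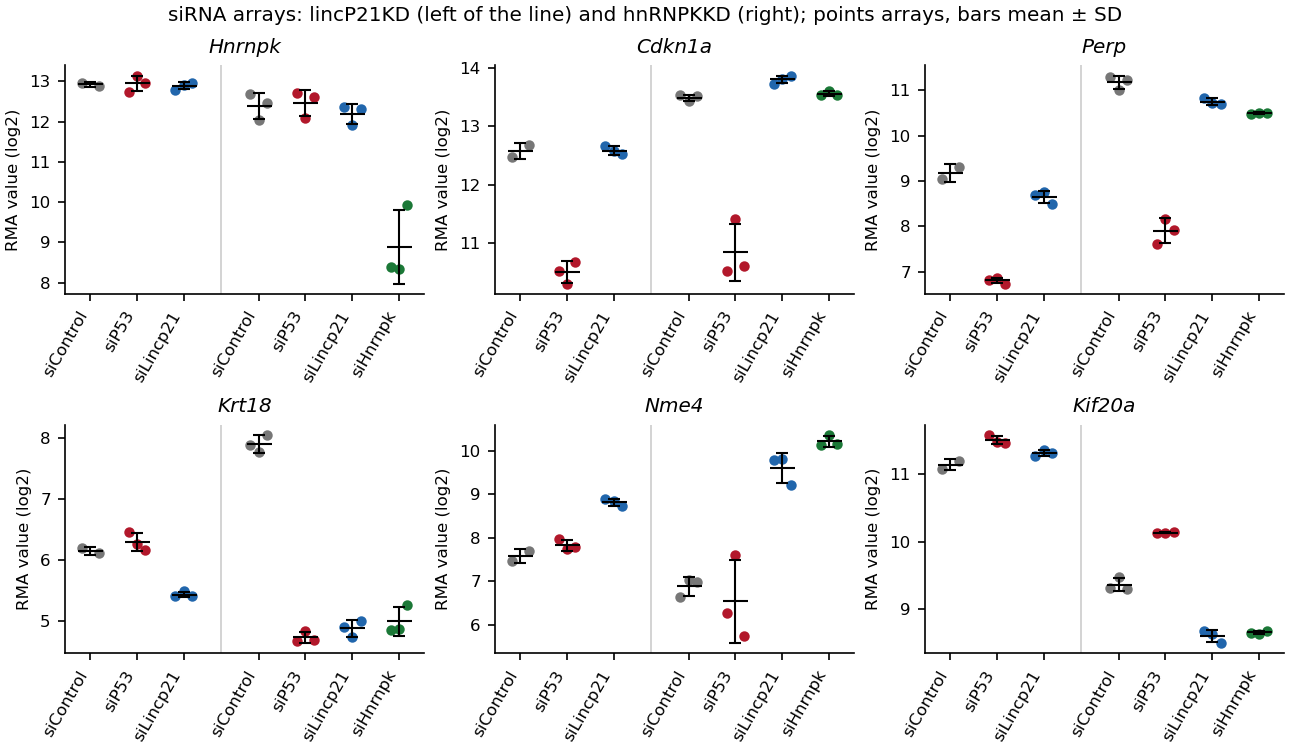
Deposited RMA log2 signal (vertical axis) of 6 genes by siRNA group (horizontal axis) in the 2 siRNA experiments; points are arrays, bars are means with standard deviations. Hnrnpk fell by 3.51 with siHnrnpk. Cdkn1a changed by -2.07 and -2.64 with siP53 in the 2 experiments. Krt18 changed by -3.16, -3.02 and -2.91 with the 3 knockdowns of the hnRNPKKD experiment.

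Genes called by all 3 knockdowns of the hnRNPKKD experiment numbered 1142, of which 464 rose and 221 fell in each, where 59.3 and 37 were expected, and 457 were mixed. With siP53, siLincp21 and siHnrnpk the changes were -3.16, -3.02 and -2.91 for Krt18, -4.15, -1.56 and -1.40 for Arg2, and -2.48, -1.96 and -1.58 for the stromelysin Mmp10. They were -1.96, -2.27 and -1.46 for Prss22, -1.52, -1.96 and -2.08 for the angiotensin receptor Agtr2, and -3.31, -1.02 and -0.89 for Tcim. Mfap5 rose by 2.19, 2.18 and 1.60 and Ednrb by 2.36, 1.92 and 1.59. The 3 knockdowns share 3 control arrays, which cannot be split into 2 groups of 2, so part of the excess may come from the shared controls. Simulated unchanged groups gave 0 shared calls, which does not measure that part among changed genes. In pairs, siLincp21 and siHnrnpk shared direction in 1533 of 1765 genes (86.9%, covariance 0.0881, simulated 0.0119), and siP53 and siLincp21 in 1563 of 2144. For siP53 and siHnrnpk it was 1059 of 1900 (55.7%), and the covariance of 0.0111 was not above the simulated 0.012. The lincP21KD experiment has other controls. Its siLincp21 calls shared direction with siHnrnpk in 503 of 654 genes, with 151 opposite (200 expected). For its siP53 calls and siHnrnpk 251 genes rose and 134 fell with both (125 and 93.2 expected), and 318 were opposite (216 expected).

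The experiments were compared directly to ask whether the same knockdown had different effects. Called genes with at least 2-fold changes numbered 932 and 143 for siP53 in the hnRNPKKD and lincP21KD experiments, and 465 and 49 for siLincp21. Own controls remove a difference in level but not one in the scale of fold changes. A difference of scale would change the size of an effect and not its sign. Whether it adds to the calls below was not tested. For siP53 1837 genes differed, 905 higher and 932 lower in the hnRNPKKD experiment, with Cemip (2.42 ± 0.31), Stk26 (2.21 ± 0.33) and Meox2 (2.04 ± 0.36) more positive and Arg2 (-3.41 ± 0.29), Krt18 (-3.31 ± 0.17) and Tgfa (-2.67 ± 0.20) more negative. The Cdkn1a effect was not called different (-0.57 ± 0.24, adjusted p = 0.123), but it was called without hnRNPKKD siP53 replicate 2 (-0.847) and with array weights (-0.906), and its adjusted p ran from 8.02e-06 to 0.34 over the alternatives. The p53 targets fell further by a median of -0.608 (13 lower and 2 higher of 38, 20 and 2 adjusted over the list alone; adjusted p = 5.11e-05, and adjusted p = 0.342 with an estimated correlation), and DNA replication genes rose further by 0.304 (14 higher of 40, 15 adjusted over the list alone; adjusted p = 4.73e-08, and adjusted p = 0.0313 with an estimated correlation). For siLincp21 1032 genes differed, 587 higher and 445 lower. Among them were Prps2 (2.11 ± 0.18), Pon2 (1.83 ± 0.13), Mreg (1.84 ± 0.27), Krt18 (-2.30 ± 0.17) and Mmp10 (-2.02 ± 0.22). Krt18 was low on the lincP21KD controls, close to the array medians, but it still changed by -0.72 with siLincp21 there. Whether its low level limited the decrease with either knockdown was not tested. Mitotic genes differed by a median of -0.628, with 21 of 31 lower and 0 higher (27 lower adjusted over the list alone; adjusted p = 5.2e-20, and adjusted p = 0.0447 with an estimated correlation), led by Kif20a (-0.93 ± 0.11) and Top2a (-0.93). DNA replication genes differed by -0.306, with 8 of 40 lower (10 adjusted over the list alone; adjusted p = 1.07e-07, and adjusted p = 0.0363 with an estimated correlation), including Gins1 (-1.02) and Mcm3 (-1.02). Without the second hnRNPKKD siP53 array 4351 genes differed for siP53, and without the first or second lincP21KD control 1074 or 936; for siLincp21 these 2 controls gave 573 and 388.

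**Figure D4:**
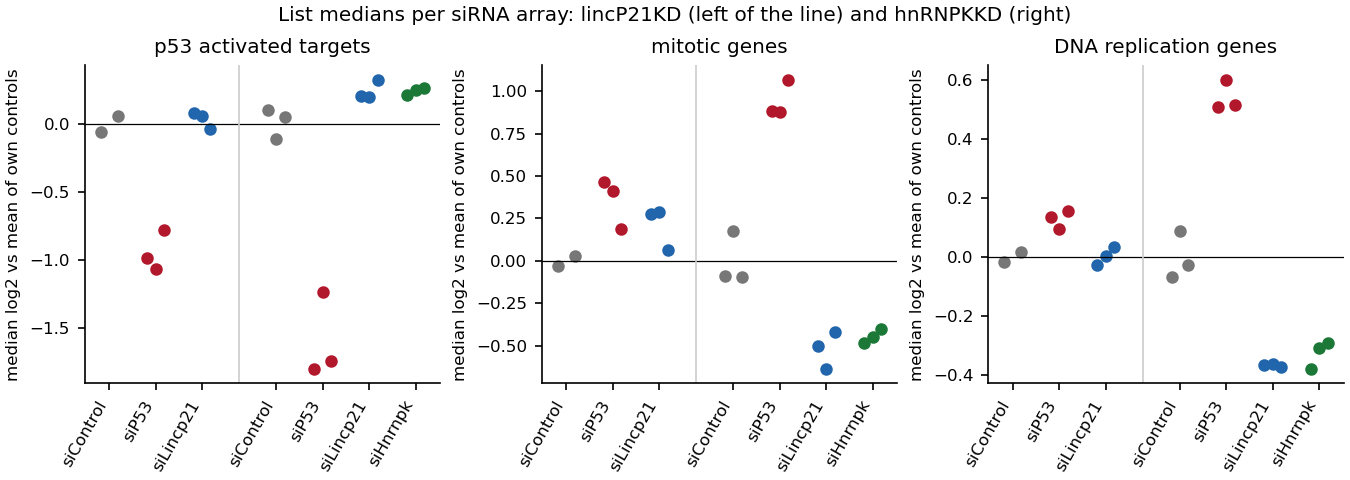
Median log2 level of p53 targets, mitotic genes and DNA replication genes on each array minus the mean of the controls of its experiment (vertical axis), by siRNA group (horizontal axis). Mitotic medians were 0.274, 0.29 and 0.063 on the siLincp21 arrays of the lincP21KD experiment and -0.504, -0.637 and -0.418 on those of the hnRNPKKD experiment.

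**Figure D5:**
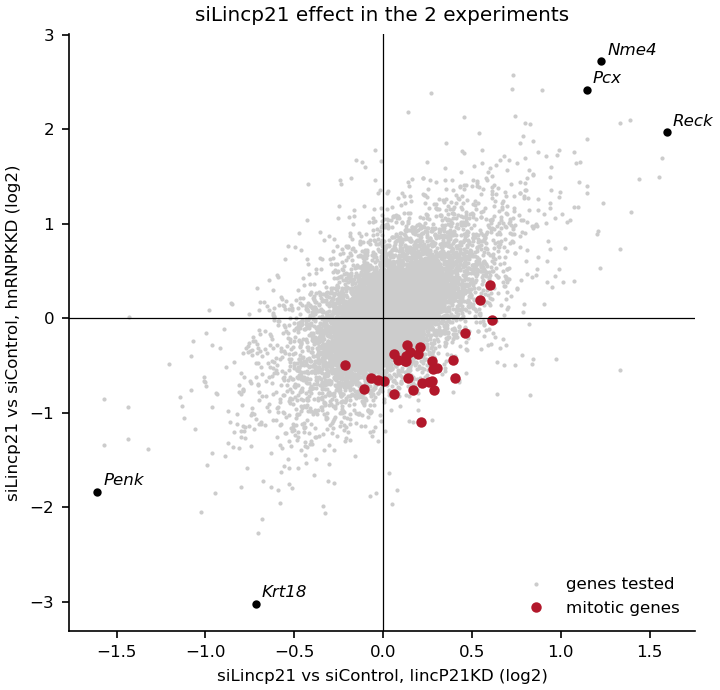
Log2 fold change with siLincp21 in the lincP21KD experiment (horizontal axis) and the hnRNPKKD experiment (vertical axis), each point a gene, mitotic genes in colour. Of 968 genes called in both, 946 shared their direction, and Nme4 rose by 1.23 and 2.72.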

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

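The test of the hnRNPKKD control arrays and the exchanges of the viruses within pairs were chosen only after the result was seen, and the other tests of this part were written before their results. The siP53 effect differed between the 2 siRNA experiments for 1837 genes by a direct test, which cannot tell a difference in the scale of fold changes from other differences. Its list medians differed by -0.608 for p53 targets, 0.57 for mitotic genes, 0.304 for DNA replication, 0.242 for DNA repair, -0.565 for interferon genes, 0.244 for matrix genes and -0.475 for NRF2 targets. Without hnRNPKKD siP53 replicate 2 the test called 4351 genes, and without lincP21KD control replicate 1 or 2 it called 1074 or 936. The DNA repair call ended without hnRNPKKD siP53 replicate 3 (0.166), lincP21KD siP53 replicate 2 (0.218) or lincP21KD control replicate 2 (0.197). With an estimated correlation DNA replication kept its call (adjusted p = 0.0313). The other calls ended, with adjusted p = 0.342 for p53 targets, 0.372 for DNA repair, 0.531 for interferon genes and 0.262 for mitotic, matrix and NRF2 genes.

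For siLincp21 the same test called 1032 genes, and 573 or 388 without lincP21KD control replicate 1 or 2. The medians differed by 0.287 for p53 targets, -0.628 for mitotic genes, -0.306 for DNA replication, -0.232 for DNA repair, 0.323 for immediate early genes, 0.142 for matrix genes and 0.341 for contractile genes. They differed by 0.472 for histones, -0.199 for proteasome genes, -0.235 for sterol genes and -0.211 for hypoxia genes. With an estimated correlation mitotic genes (adjusted p = 0.0447), DNA replication (adjusted p = 0.0363) and hypoxia genes (adjusted p = 0.0363) kept their calls. The others ended, with adjusted p = 0.435 for p53 targets, 0.302 for DNA repair and histones, 0.217 for immediate early and contractile genes, 0.307 for matrix, 0.265 for proteasome and 0.54 for sterol genes. The contractile call ended without hnRNPKKD siLincp21 replicate 1 (0.306) or control replicate 1 (0.247), and the sterol call without hnRNPKKD control replicate 2 (-0.126) or lincP21KD siLincp21 replicate 3 (-0.133). The histone call ended without hnRNPKKD siLincp21 replicate 1 (0.472) or 3 (0.404), hnRNPKKD control replicate 1 (0.469) or 2 (0.446), lincP21KD siLincp21 replicate 1 (0.427) or 2 (0.481), or lincP21KD control replicate 2 (0.368).

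The time response differed between the viruses for 23 genes by the interaction test. Median slopes differed by 0.106 per h for p53 targets, -0.044 for mitotic genes, -0.07 for DNA replication, 0.151 for histones and -0.082 for sterol genes. With an estimated correlation all 5 list calls ended (adjusted p = 0.745 for mitotic genes and 0.459 for the other 4). Without 0, 1, 3 or 9 h the test called 0, 0, 3 or 7 genes. The mitotic call ended without 0 h (-0.048) or 9 h (-0.022) and the histone call without 9 h (0.133).

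For the interaction count of 23, chance could not be excluded, since 5 of 100 splits of the 10 arrays gave as many calls and the highest other split gave 601. That split exchanged the viruses at 6 and 9 h, so the virus effect itself entered the slope, a structure of the samples. Among the 16 exchanges within the 5 pairs 3 gave as many calls, too few splits for a share under 0.05. The virus effect gave its 2427 calls in 1 of 100 free splits with 0 in the highest other. Free splits break the pairing by time, and in the others the virus effect itself enters the spread. They therefore cannot exclude chance. The exchanges within pairs, which keep the design, are too few at 16 (real 2427, highest other 0). Without the 3, 6 or 9 h pair the virus gave 1146, 1444 or 1511 calls. For siP53 (4888 calls), siLincp21 (3678) and siHnrnpk (3408) in the hnRNPKKD experiment the 10 splits were too few for such a test, the real split being 1 of 10 and the highest other calling 0 each time.

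With siLincp21 6 of 31 mitotic genes rose in the lincP21KD experiment and 19 of 31 fell in the hnRNPKKD experiment, with list calls that ended with an estimated correlation (adjusted p = 0.668 and 0.162). Leaving out any of the 11 arrays concerned turned the sign of the median in 0 fits, with medians of 0.148 to 0.282 and -0.555 to -0.446, which argues against 1 array as the cause. Whether the hnRNPKKD controls alone were high in mitotic genes stays open. The siLincp21 and siHnrnpk arrays differed by a median of only -0.029 there, and siP53 lay above the controls by 0.923, which decides nothing because siP53 raised these genes in the lincP21KD experiment too (0.364). A biological difference between the cultures of the 2 experiments, whose dose, time and virus were given alike, also stays open.

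Of the genes called in 1 direction by all 3 hnRNPKKD knockdowns, 590 of 685 had the same sign with siLincp21 in the lincP21KD experiment, which used other control arrays. That share of 0.861 stands beside 87.5% for genes called by siLincp21 alone and 68.6% for all 12674 genes. For siP53 83.8% of the 685 genes stand beside 83.9% of those called by siP53 alone, and the share over all genes was not computed. These shares argue against the levels of those 3 control arrays as the whole cause of the siLincp21 and siP53 calls. They do not show that the overlap is a shared effect, and siHnrnpk has no other experiment. An effect of the control siRNA itself, if it was used in both experiments, was not tested and stays open. Krt18 fell in both siLincp21 comparisons but was not lower with siP53 in the lincP21KD experiment, where its levels were 6.46, 6.26 and 6.17 beside 6.2 and 6.11.

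The second siP53 array of the hnRNPKKD experiment lay between the other siP53 arrays and the controls in p53 targets (median -1.238, others -1.798 and -1.742) and Cdkn1a (11.41, others 10.52 and 10.61). In mitotic genes it was close to the nearer of them (0.878, others 0.886 and 1.068), and in DNA replication genes it lay above both (0.601, others 0.508 and 0.514). Over the 1615 genes called in the lincP21KD experiment its slope on the other 2 siP53 arrays was 0.804, which argues against a control array under a wrong label. Slopes of 0.569 for genes that rose and 0.623 for genes that fell differed by 0.054, as 1 factor for all genes such as a weaker knockdown or admixed control RNA would give, but of 8 lists called for siP53 5 were smaller and 2 larger on this array, so this stays open. Whether the replicate 2 arrays differ as a set and whether RNA quality plays a part (actin 3′ minus 5′ signal 0.165, others 0.691 and 1.14) also stay open, as 1 of the other 3 groups correlated under 0.3 (siControl 0.359, siLincp21 0.631, siHnrnpk 0.189).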

How the results depend on the processing

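The actin covariate was chosen after the data were seen, and the other settings were written beforehand. Leaving out arrays or times in turn gave 1146 to 2055 calls for the virus (2427 with all), 0 to 0 for the AdenoGFP slope (1), 204 to 424 for the AdenoCre slope (684) and 0 to 19 for the interaction (23). It gave 620 to 1313 for siP53 (1615) and 286 to 1377 for siLincp21 (1503) in the lincP21KD experiment, and 3821 to 6553, 2827 to 3081 and 2391 to 2918 for siP53 (4888), siLincp21 (3678) and siHnrnpk (3408) in the hnRNPKKD experiment. Differences between experiments ranged from 936 to 4351 for siP53 (1837) and from 388 to 898 for siLincp21 (1032). Genes shared in direction ranged from 88 to 511 for the lincP21KD pair (472) and from 473 to 973 for the hnRNPKKD knockdowns (685), and list calls from 86 to 103 (97).

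With at least 1.5-fold the virus kept 982 calls, siP53 551 and siLincp21 409 in the lincP21KD experiment, 2572, 1688 and 1588 for siP53, siLincp21 and siHnrnpk in the hnRNPKKD experiment, and 103 and 253 shared genes. At an adjusted p below 0.01 the counts were 734 for the virus, 199 for the AdenoCre slope, 1 for the interaction, 738 and 528 in the lincP21KD experiment, 3258, 2289 and 2082 in the hnRNPKKD experiment, 857 and 419 for the differences, and 153 and 372 shared. Requiring only an unadjusted p in the other knockdown gave 962 shared genes in the lincP21KD experiment.

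Array weights gave 2430 calls for siLincp21 in the lincP21KD experiment, 8869, 5663 and 5753 in the hnRNPKKD experiment, 6258 and 2797 for the differences, 792 and 1529 shared, and 1 for the interaction. The actin covariate gave 5683 for siLincp21 and 5463 for siHnrnpk, 2302 for the siLincp21 difference and 1208 shared. Fits of the compared groups alone gave 924 for the siP53 difference. Without the time block the virus gave 1304. With log2 hours the slopes gave 439 for AdenoCre and 0 for AdenoGFP, where limma had 1654 at an unadjusted p below 0.05 on hours, and the interaction 5. The interaction gave 9 with the 60% filter, 36 after quantile scaling, 43 after centring and 41 with trend and robust variances, and the AdenoGFP slope 2 after either scaling.

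With an estimated correlation camera called 4 lists instead of 97. DNA repair and checkpoint genes changed the direction of their test for the AdenoGFP slope without 9 h, with a median of 0.006 per h beside 0.042, and left-out times gave medians of 0.006 to 0.069. Cdkn1a with siLincp21 in the lincP21KD experiment, which did not pass at 0.007, had the other sign after quantile scaling (-0.006) and centring (-0.048), and ranged from -0.092 to 0.105 over left-out arrays. The cause was not tested for any of these changes.

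Outside siHnrnpk and its controls, no 2 groups had all 3 pairs over 0.1, and the labels give only a shared number. Single pairs there were still correlated. For siLincp21 and siP53 of the hnRNPKKD experiment the values were -0.0328, 0.631 and 0.694 for replicates 1, 2 and 3. The hnRNPKKD correlations ran from -0.206 to 0.694 with 11 of 18 over 0.1, and the lincP21KD ones from -0.218 to 0.341 with 3 of 7. A replicate block gave 1790 and 1476 calls for siP53 and siLincp21 in the lincP21KD experiment, 5426, 4161 and 3824 in the hnRNPKKD experiment, 1937 and 1116 for the differences, 507 and 784 shared and 99 list calls. Under the block 4 lists had no call: neural markers for siP53 (0.175) and chromatin (-0.058) and epithelial genes (-0.131) for siLincp21 in the lincP21KD experiment, and sterol genes for the siLincp21 difference (-0.108). It ended no other list call. Cdkn1a with siLincp21 in the lincP21KD experiment was -0.021 under the block.

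In simulated data 1.5-fold, 2-fold and 4-fold changes were recovered more often in the virus and knockdown comparisons than in the slopes, and least often in the interaction, whose low count is therefore no sign that slopes were alike.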

Other observations

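The sets of p53-responsive genes of this part were chosen after the data were seen, and the marker values come from lists fixed earlier. The neural genes Map2 and Tubb3 rose in several knockdowns. Map2, a microtubule-associated protein of neurons, rose by 1.15 and 1.40 with siLincp21 in the lincP21KD and hnRNPKKD experiments and by 0.77 with siHnrnpk, and Tubb3 by 1.02, 0.75 and 1.73 in the same comparisons. With siHnrnpk 5 of 10 neural markers rose and 0 fell in both counts, including the neurofilament gene Nefm (1.76 ± 0.13). Their median was 0.271 (adjusted p = 0.0147, and adjusted p = 0.259 with an estimated correlation). With siLincp21 the neural list was not called in the lincP21KD experiment (2 of 10 rose, 3 adjusted over the list alone, median 0.028, adjusted p = 0.439). It was not called in the hnRNPKKD experiment either (3 rose and 1 fell in both counts, median 0.101, adjusted p = 0.444). Of 5 adipocyte markers 1 rose and 2 fell with siHnrnpk in both counts (median -0.564, adjusted p = 0.63). The cartilage collagen gene Col11a1 rose by 2.10 with siLincp21 and fell by 2.03 with siHnrnpk, a difference that was not tested directly. Rfc1 rose in every siRNA comparison, by 1.03 and 1.15 with siP53 and siLincp21 in the lincP21KD experiment and by 1.51, 1.32 and 1.22 with siP53, siLincp21 and siHnrnpk in the hnRNPKKD experiment, while 18 of 40 DNA replication genes fell with each of the last 2.

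Single markers moved in opposite directions with p53 restoration and with p53 knockdown. The lysosomal macrophage marker Cd68 rose by 0.81 with restoration and changed by -1.81 and -2.63 with siP53 in the lincP21KD and hnRNPKKD experiments. Pdgfra fell by 1.88 with restoration and rose by 0.52 with siP53 in the lincP21KD experiment, where it did not pass without control replicate 2 (0.447).

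Genes repressed by p53, called lower with restoration and higher with siP53 of the hnRNPKKD experiment, numbered 406. Of these 94 rose with siLincp21 in the lincP21KD experiment (23.2%, other genes 6.95%; camera p = 1e-05, and p = 0.0909 with an estimated correlation). Of the 855 genes activated by p53 in the same sense 5.61% rose there (other genes 7.61%) and 9.12% fell (other genes 4.04%; camera p = 0.0244, and p = 0.436 with an estimated correlation). Genes activated by p53, defined in the same way with siP53 of the lincP21KD experiment, numbered 387, and 138 of them rose with siHnrnpk (35.7%, other genes 13.4%; camera p = 3.26e-05, and p = 0.276 with an estimated correlation). Of the 232 repressed genes 17.7% rose with siHnrnpk (other genes 14%), a set that camera did not call. With siLincp21 in the hnRNPKKD experiment 28.4% of the 232 repressed genes rose, beside 17% of other genes (camera p = 0.0276, and p = 0.469 with an estimated correlation). The 387 activated genes did the same there, with 28.4% rising beside 16.8% of other genes (camera p = 0.0457, and p = 0.59 with an estimated correlation). In this comparison the rise was thus not particular to repressed genes. Of 982 genes called there and by restoration, 531 rose and 141 fell in both (281 and 93.6 expected), and 310 were opposite (329 expected). For siHnrnpk 481 rose and 171 fell in both (230 and 101 expected), and 301 were opposite (321 expected). For siLincp21 of the lincP21KD experiment 155 rose and 48 fell in both (122 and 34.7 expected), and 242 were opposite (131 expected).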
